A study of Homo sapiens with 3 samples.

How the data were processed

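3 arrays were analysed, 1 each for full-length, HIS-tagged human RUNX1, RUNX3 and HOXB13, detected with Alexa647 and scanned at 635 nm. Per the labels' protocols the proteins were purified from E. coli or obtained commercially. Each array has 20250 spots, of which 19320 carry the designed oligonucleotides under 840 names with 23 copies each, 845 are empty and 85 carry calibration oligonucleotides. Names with an identical sequence were pooled, which gives 722 distinct sequences. The oligonucleotides are 60 bases long and fold into a hairpin with a 20 bp stem and a loop of 4 bases. In the sequences X stands for 5mC. Per the file headers, 1479 probe spots of the RUNX3 array (7.66%) were flagged and have no value, and none were flagged on the other arrays, so sequences have 15 to 108 spots on RUNX3 and 23 to 115 elsewhere.

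The deposited values are spot intensities on a linear scale. The authors' deposited foreground median intensity is spatially corrected: from the values, each equals the raw median times the median of the array over the median of a 9 by 9 window of probe spots, within a tolerance of 0.0001 in 100% of spots with a value. In the central 95% of spots the ratio of raw to corrected intensity ran from 0.53 to 2.02 on the RUNX3 array, 0.77 to 1.24 on RUNX1 and 0.63 to 1.52 on HOXB13. The deposited series values equal this column. The scanner's saturation column gives, per the file headers, the percent of saturated foreground pixels, and 71 RUNX1, 537 RUNX3 and 50 HOXB13 probe spots had any. The scanner software and its version are not given in the sources used here. The signal of 78.2% of the RUNX1 probe spots, 25.5% of RUNX3 and 2.59% of HOXB13 lay below the local background, so background subtraction would leave no log value. The plan fixed beforehand named a background-subtracted column and no spatial correction. The corrected foreground without subtraction was used in its place, and the planned spatial correction became the reverse, spots before the correction.

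All tests used log2 of the corrected intensity. A pair is a variant and its reference, which differ by a base pair, by 5mC, or by the methylation of a CpG. 267 substitution pairs, 117 pairs with 5mC outside CpG, 167 hemi-methylated and 77 fully methylated CpG pairs and 18 pairs with 5mC outside the site were formed. Another 9 sequences with several 5mC outside the design's pairs were not tested. For substitutions within sites 1, 2 and 3, the same pair of sequences can serve in both directions, and variants of a site share the chance values of its reference. Site 2 was also printed in the opposite orientation (the flipped site), so counts over pairs hold many changes of this duplex in each orientation. A pair was tested where its mean lay above the 95th percentile of the 30 randomized controls, of which 14 hold 5mC and 16 do not. For references near or under that percentile this filter keeps rises and drops falls. Counts of lower and higher pairs therefore lean to rises at weakly bound sites. limma 3.58.1 in R 4.3.3 (lmFit and eBayes per array and class) compared the spots of the 2 sequences, two-sided, with Benjamini-Hochberg adjustment within array and class at 0.05. With 1 array per protein, p-values measure only the spread between spots of an array, and the number of arrays limits the precision. The difference between arrays was tested as an interaction in limma over pairs tested on both. The signal above the controls was the mean linear intensity minus the median of the controls' mean intensities, and its 95% interval came from resampling spots. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest.

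The steps were tested on simulated data with the real numbers of spots and spot SDs, in which every pair had its own reference, so the sharing of references was not simulated. In the RUNX1 substitution step (124 pairs), 24 of 24 planted changes of 0.5 and 22 of 24 of 0.25 were recovered. In the RUNX3 substitution step (78 pairs) these were 14 of 14 and 9 of 14, in the HOXB13 substitution step (99 pairs) 18 of 18 and 18 of 18, and in the RUNX3 step for 5mC outside CpG (21 pairs) 4 of 4 and 1 of 4. No unchanged pair was called in any step.

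The sequences named were chosen by a rule fixed before the data were examined: on each array up to 5 bound sites of highest intensity, in each class the 3 largest increases and 3 largest decreases past the threshold whose every variant spot lay on that side of the reference mean, and the CpG states of bound sites that hold TGCGGT (RUNX arrays) or TTTACG (HOXB13). Every other pair printed was chosen after its values were seen, and changes that turn a bound site into another and the same states in the flipped site were added beside them for comparison. The alternatives were normexp background correction with offset 50, spots before the spatial correction, flagged spots kept, saturated spots removed, the series values, the 99th percentile or no filter, a permutation test over spots with 100000 resamples, a difference of at least 1.5-fold, and leaving out each of the 23 spot copies. For sites the median of spots was used, for arrays pairs with both sequences above the threshold and differences divided by the array's range, and for lists unmethylated sequences. A filter from the controls without 5mC and removal of the controls' GC trend were added after the data were seen.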

Results

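The series measured how purified human transcription factors bound double-stranded DNA oligonucleotides printed on a glass array, with and without 5-methylcytosine (5mC) at chosen bases. 3 proteins were each applied to 1 array: RUNX1 and RUNX3, related Runt-domain factors that read TGTGGT-like cores, and HOXB13, a homeodomain factor that reads TTTATT-like or TTTACG-like cores. Each protein was full-length and HIS-tagged, and binding was read as the fluorescence of a single dye. Every printed oligonucleotide folded back on itself into a hairpin with a 20 bp stem. The stem carried a binding site of known type in which every position was changed to every other base, to a 5mC:G pair on either strand, or, with its neighbour, to a CpG that was unmethylated, methylated on 1 strand (hemi-methylated) or methylated on both strands (fully methylated). The array held 722 distinct sequences built on 8 sites, plus 30 randomized controls among them, and each sequence was printed 23 to 115 times. The sequences are synthetic and have no place in a genome.

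On the RUNX1 array the randomized controls had a median log2 intensity of 10.77 and a 95th percentile of 11.08, and 221 of the 722 sequences lay above that percentile. On the RUNX3 array these values were 12.25 and 12.60, with 125 sequences above. On the HOXB13 array they were 11.98 and 12.07, with 187 sequences above. The distance from the control median to the brightest sequence was 2.73 log2 units for RUNX1, 1.47 for RUNX3 and 0.62 for HOXB13, while the median SD between replicate spots was 0.14, 0.29 and 0.12. On the RUNX3 array the level of the 30 controls rose with their GC content, by 0.20 log2 units per 10 percentage points (r = 0.92 across controls). The slope was 0.09 for RUNX1 (r = 0.65) and 0.01 for HOXB13 (r = 0.21). Over the 16 controls without 5mC it was 0.20 for RUNX3 (r = 0.95), 0.02 for RUNX1 (r = 0.23) and 0.04 for HOXB13 (r = 0.46). The controls with 5mC were richer in GC, so the RUNX1 trend over all 30 is not separate from 5mC. Intensities include the background of the slide, so a log2 difference understates the change of the protein-dependent signal. For that reason the signal of a variant above the median intensity of the controls is also given as a percentage of the same signal of its reference, with a bootstrap interval over spots. The replicate spots of an array are technical replicates, so every error and adjusted p below describes the spread between spots of that array and not between repeated binding experiments.

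The first comparison asked which unmodified sites each protein bound above the randomized controls. RUNX1 bound 4 sites. RUNX site 2, TGTTGCGGTTG, which holds a CpG in its core, was the strongest at 12.46 ± 0.34 (SD, n = 115 spots), 3.23-fold over the control median, and the same duplex printed in the opposite orientation, CAACCGCAACA, reached 12.38 ± 0.23 (SD, n = 46 spots). RUNX site 3, TGTTGTGGTTG, which has no CpG, reached 11.64 ± 0.12 (SD, n = 46 spots), and RUNX site 1, TGTCGCGGTTG, which has a pair of CpGs, reached 11.34 ± 0.16 (SD, n = 115 spots). RUNX3 bound the flipped site 2 at 13.19 ± 0.38 (SD, n = 41 spots), site 2 at 13.06 ± 0.42 (SD, n = 108 spots) and site 1 at 12.64 ± 0.39 (SD, n = 105 spots). The site 1 value on the RUNX3 array fell below the 99th percentile of the controls, 12.71. RUNX site 3 on the RUNX3 array, at 12.40, lay under the 95th percentile, but above it when the GC trend of the controls was removed. HOXB13 bound HOXB13 site 2, GTTTTACGAGG, at 12.39 ± 0.17 (SD, n = 46 spots) and HOXB13 site 1, GTTTTATTGGG, at 12.38 ± 0.17 (SD, n = 23 spots), 1.33-fold and 1.31-fold over the control median. A site of the zinc-finger factor MTF1, GCCGGGTGCAG, also lay above the controls on the HOXB13 array, at 12.19 ± 0.11 (SD, n = 46 spots). A longer RUNX site, TTCTGTGGGCTG, lay above the 95th percentile of all controls on none of the arrays. For RUNX1 this site, at 10.94, and the MTF1 site, at 10.96, lay above the threshold when it was taken from the controls without 5mC or when the GC trend was removed.

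Orientation was compared by printing RUNX site 2 and its variants in both directions within the same flanks. Across 85 duplexes present in both orientations, the mean log2 intensities correlated at r = 0.99 (rho = 0.98) for RUNX1 and r = 0.93 (rho = 0.92) for RUNX3, and at r = 0.35 (rho = 0.32) for HOXB13, which did not bind this site. The median absolute difference between orientations was 0.08 for RUNX1 and 0.11 for RUNX3. These correlations are across sequences, which are not independent replicates.

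Single-base substitutions showed which positions each protein required. On the RUNX1 array 89 of 124 tested substitutions lowered the signal and 23 raised it (limma over spots, adjusted p under 0.05), and 12 did not pass. Of the falls 25 were in site 2 and 25 in the flipped site, so changes of the same duplex are counted in each orientation. In RUNX site 2 every substitution from position 3 to position 10, counted from 1 at the 5′ end of the printed site, lowered the RUNX1 signal. At positions 5, 7 and 8 every variant lay at the level of the controls, between 10.66 and 10.82, so the order of falls among these positions is not resolved. G7A fell by 1.80 (SE 0.07, adjusted p = 1.02e-52), G7C by 1.79 (SE 0.05, adjusted p = 1.51e-75) and G8A by 1.77 (SE 0.07, adjusted p = 6.68e-52), each to the level of the controls, with -3.19%, -2.87% and -2.24% of the site's signal left. Position 6 depended on the base: C6T, which turns site 2 into site 3, fell by 0.82 and left 36.2% of the signal (95% interval 33.7 to 39.0), whereas C6A and C6G, named after their values were seen, fell by 1.55 each and left 4.84% and 4.54%. At the last position the signal rose: G11T increased it by 0.72 (SE 0.07, adjusted p = 1.18e-17), and in the flipped site C1T and C1A increased it by 0.98 (SE 0.06, adjusted p = 2.92e-25) and 0.78 (SE 0.05, adjusted p = 1.94e-22). G11A of site 2, at 13.50 ± 0.27 (SD, n = 23 spots), was the brightest sequence on the RUNX1 array, singled out after its value was seen. G11C instead lowered site 2 by 0.49. The same direction by base was seen in site 3, where G11A raised the signal by 0.70, G11T by 0.58, and G11C lowered it by 0.33. The G11C change of site 2 and the changes of site 3 were likewise chosen with their values known. In RUNX site 1 the largest gain was C4T at 1.12 (SE 0.03), which turns site 1 into site 2.

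On the RUNX3 array 46 of 78 tested substitutions lowered the signal, 7 raised it and 25 did not pass. All the falls were in 1 duplex, 22 in site 2 and 24 in the flipped site. In the flipped site 2 falls to about the level of the controls were seen, C7T by 1.08 (SE 0.11, adjusted p = 2.14e-22), C5T by 1.02 (SE 0.11, adjusted p = 1.30e-20) and G6T by 0.99 (SE 0.11, adjusted p = 4.04e-19), with -11.2%, -5.64% and -5.81% of the site's signal left. G11A of site 2 rose by 0.50 (SE 0.09, adjusted p = 1.03e-07) and C1T of the flipped site rose by 0.53 (SE 0.10). Site 1 and site 3 had few testable pairs on this array, 13 and 1. In both 0 were lower and 1 was higher, but the filter drops falls from references this close to the threshold or under it. With spots taken before the authors' spatial correction, 26 RUNX3 substitutions of 49 tested passed in place of 53, and with normexp background correction 31.

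**Figure D1:**
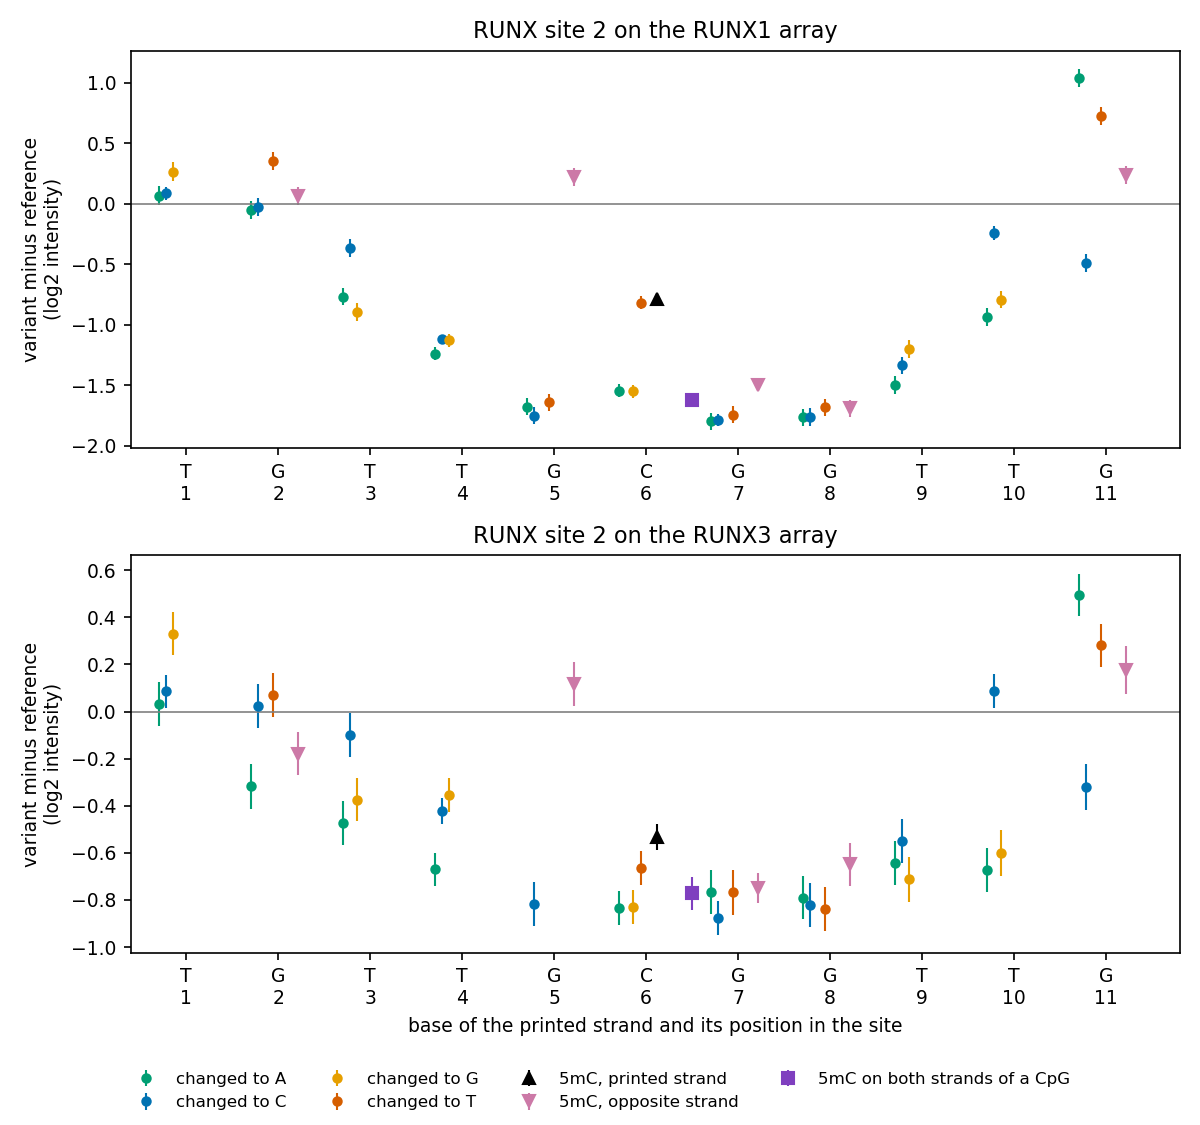
Changes of log2 intensity for variants of RUNX site 2 against the unmodified site on the RUNX1 array (top) and the RUNX3 array (bottom), by position in the site. Circles are base substitutions coloured by the new base, triangles are 5mC on the printed or the opposite strand, and the square is the core CpG methylated on both strands. Bars are the SE from limma over spots, and only pairs that passed the filter are drawn. On the RUNX1 array substitutions at positions 3 to 10 lie below 0, and 5mC opposite position 8 lies at -1.69 while 5mC opposite position 5 lies at 0.22.

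On the HOXB13 array 60 of 99 tested substitutions lowered the signal and 0 raised it. limma gave 0 increases at an unadjusted p under 0.05 too, as did the permutation test over spots. The named changes at position 6 of the HOXB13 sites ended below the control median: A6T fell by 0.55 in site 1 (SE 0.04, adjusted p = 5.30e-18) and by 0.55 in site 2 (SE 0.04, adjusted p = 1.22e-21), and A6C in site 2 fell by 0.53 (SE 0.04, adjusted p = 8.14e-21). The intensities after them stood at -33.6%, -26.9% and -23.5% of the site's signal above the controls, so the size of these falls does not rank position 6 against other positions whose variants end at the controls. The smallest changes at position 6 were -0.38 in site 1 and -0.35 in site 2, and neither ended below the control median. At position 11 of both sites none of the 3 changes passed, whereas at position 1 G1C fell by 0.24 in site 1 (SE 0.05) and by 0.18 in site 2 (SE 0.04), named after their values were seen. In site 2, C7T, which removes the core CpG, changed the signal by -0.10, against -0.37 for C7A and -0.42 for C7G, which were chosen with their values known. In the MTF1 site 9 of 33 substitutions passed, with a largest change of -0.11. No HOXB13 substitution reached 1.5-fold, and 25 of the 93 tested passed with spots taken before the spatial correction.

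5mC outside CpG was then compared with unmethylated C at the same place, the question named in the series title. On the RUNX1 array 8 of 40 tested pairs were lower with 5mC and 10 were higher. A methyl group on the strand opposite position 8 of the core, in a CC context, brought the signal to the level of the controls: it fell by 1.69 in site 2 (SE 0.07, adjusted p = 4.75e-50), by 1.48 in the flipped site (SE 0.05, adjusted p = 5.21e-40, position 4 of that printed strand) and by 0.96 in site 3 (SE 0.04, adjusted p = 3.84e-37). The signal left was -0.07% (95% interval -1.40 to 1.39), 4.58% (2.13 to 6.95) and -6.71% (-12.4 to 0.23) of the unmethylated site's. In site 3, 5mC opposite position 7 lowered the signal by 0.84 (SE 0.03), a pair named after its value was seen. It left 3.05% of the signal, so positions 7 and 8 are not ranked by these falls. The increases were smaller, between 0.11 and 0.33. The 0.33 (SE 0.06) came from 5mC at position 10 of the flipped site, but the same cytosine in site 2, opposite position 2, did not pass, at 0.07 (SE 0.08, adjusted p = 0.47), nor did it in site 3, at 0.01 (SE 0.03, adjusted p = 0.76). The others included 5mC opposite position 5 in site 2, at 0.22 (SE 0.07), and in site 3, at 0.24 (SE 0.03), and 5mC at position 7 of the flipped site, the same cytosine in the opposite orientation, at 0.27 (SE 0.06). Opposite position 11 the increases were 0.24 in site 2, 0.13 in site 1 and 0.11 in site 3, but the same cytosine in the flipped site, at position 1, did not pass, at 0.06 (SE 0.06, adjusted p = 0.40). These increases were named after their values were seen, and none reached 1.5-fold. 5mC in the flanks of site 1 also gave called rises on this array, of 0.10 to 0.24, but only that of 0.15 left the bases unchanged. Rises of about this size thus also occurred outside the site. By context 10 of 19 CA, 6 of 12 CC and 2 of 9 CT pairs passed.

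On the RUNX3 array 2 of 21 pairs passed and both were lower: the signal fell by 0.65 in site 2 (SE 0.09, adjusted p = 1.71e-10) and by 0.82 in the flipped site (SE 0.10, adjusted p = 4.86e-13), at the same cytosine opposite position 8, leaving 15.4% (0.16 to 35.4) and 6.16% (1.74 to 10.7) of the signal. No pair rose on this array by limma or by the permutation test, and 1 had a higher signal at an unadjusted p under 0.05. On the HOXB13 array 3 of 33 pairs passed, all named after their values were seen, since not every spot of the variant lay on the same side of the reference mean. 5mC opposite position 8 in the T8G variant of site 1, in a CA context, raised the signal by 0.32 (SE 0.05, adjusted p = 1.74e-07) to 12.60, the brightest sequence on that array, or 238% (182 to 322) of the unmethylated variant's signal. 5mC opposite position 9 in the A9G variant of site 2 raised it by 0.17 (SE 0.03). 5mC opposite position 10 of site 2 lowered it by 0.23 (SE 0.04), to 39.2% (24.4 to 54.4) of the signal. At the same position of site 1 the change did not pass limma, at -0.11 (SE 0.05, adjusted p = 0.15). None of the 3 HOXB13 pairs that passed did so with spots taken before the spatial correction.

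CpG methylation was compared state by state in the bound sites. In RUNX site 2, whose core CpG spans positions 6 and 7, full methylation lowered the RUNX1 signal by 1.62 (SE 0.05, adjusted p = 1.32e-69) and left 2.13% (0.70 to 3.50). Hemi-methylation depended on the strand. A methyl group on the opposite strand at position 7 lowered the intensity to 0.353 of the unmethylated site's (adjusted p = 8.66e-83) and left 6.11% (5.06 to 7.16), whereas a methyl group on the printed strand at position 6 lowered it by 0.78 (SE 0.04, adjusted p = 2.05e-49) and left 38.4% (35.9 to 41.1). The flipped site gave the same order, with falls of 1.48 for both strands, 1.35 for the cytosine that corresponds to position 7 and 0.80 for the one that corresponds to position 6. RUNX3 gave falls in site 2 of 0.77 (SE 0.07), 0.75 (SE 0.06) and 0.53 (SE 0.06), and in the flipped site 0.78 (SE 0.09), 0.72 (SE 0.08) and 0.55 (SE 0.08), in the same order of states. All of these passed limma on both arrays.

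RUNX site 1 holds a second CpG, at positions 4 and 5, beside the core CpG. The core TGCGGT of site 2 begins at position 4, where site 1 has C in place of T. 5mC at position 4 of this CpG raised the signal. For RUNX1, full methylation of positions 4 and 5 raised site 1 by 0.96 (SE 0.03, adjusted p = 4.61e-78), to 393% (364 to 427) of the unmethylated signal. A methyl group on the printed strand at position 4 alone gave 0.83 (SE 0.02) and 1 on the opposite strand at position 5 gave 0.09 (SE 0.02). The cytosine of position 5 in the flipped site gave -0.05 (SE 0.11, adjusted p = 0.72). In the flipped site the A8G change makes the same duplex, and 5mC at position 8 of its opposite strand raised it by 0.91 (SE 0.08, adjusted p = 1.27e-18). The unmethylated A8G sequence held a saturated spot far above its other spots, and with saturated spots removed the increase was 0.98. In site 3 the T4C change makes this CpG, and full methylation raised it by 0.60 (SE 0.03, adjusted p = 8.76e-33). For RUNX3 the increases were 0.31 (SE 0.06) for position 4 and 0.29 (SE 0.06) for both strands in site 1. For the same states in the flipped site they were 0.64 (SE 0.07) and 0.50 (SE 0.08). In the T4C variant of site 3 full methylation changed the RUNX3 signal by 0.04 (unpooled SE 0.07). That pair lay under the filter and was not tested on that array. 5mC at position 5 alone did not pass on that array, at -0.01 (SE 0.06, adjusted p = 0.87) in site 1 and -0.03 (SE 0.09, adjusted p = 0.87) in the flipped site.

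All 16 methylation states of the pair of CpGs in site 1 were printed. For RUNX1 the 8 states with 5mC at position 7 lay between 10.77 and 10.93, all under the 95th percentile of the controls, and the other 8 between 11.05 and 12.30, of which the state with 5mC at position 6 alone also lay under it. Adding 5mC at position 4 changed the signal by 0.83 (SE 0.02) when no other cytosine was methylated. The change was 0.31 (SE 0.03) when position 6 was methylated and 0.05 (SE 0.03) when position 7 was. The starting levels lay 0.57, 0.28 and 0.05 above the control median. Near the controls a log2 step understates the change of signal, so these steps do not measure how far core methylation cancels the gain. With positions 5 and 7 methylated the change was 0.14 (SE 0.05). With 5mC at positions 4, 5 and 6 the level was 11.64 ± 0.21 (SD, n = 23 spots), above the unmethylated 11.34. For RUNX3 the 8 states with 5mC at position 7 lay between 12.27 and 12.54, all under the 95th percentile of 12.60, and the other 8 between 12.45 and 12.95, so the ranges overlapped. On that array 5mC at position 4 gave 0.31 (SE 0.06) alone and 0.11 (SE 0.07) with position 6 methylated. With position 7 methylated it gave -0.20 (SE 0.07). The limit on comparing log2 steps near the controls applies to these values too. The pair of site 1 with and without 5mC at position 7 fell just under the filter on the RUNX1 array. Without the filter it fell by 0.52 (SE 0.02, adjusted p = 6.94e-56), and on the RUNX3 array it changed by -0.09 (SE 0.06, adjusted p = 0.55). 5mC at position 6 and on both strands of the core passed without the filter on both arrays, at -0.29 and -0.57 for RUNX1 and at -0.18 (adjusted p = 0.024) and -0.23 (adjusted p = 0.020) for RUNX3.

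**Figure D2:**
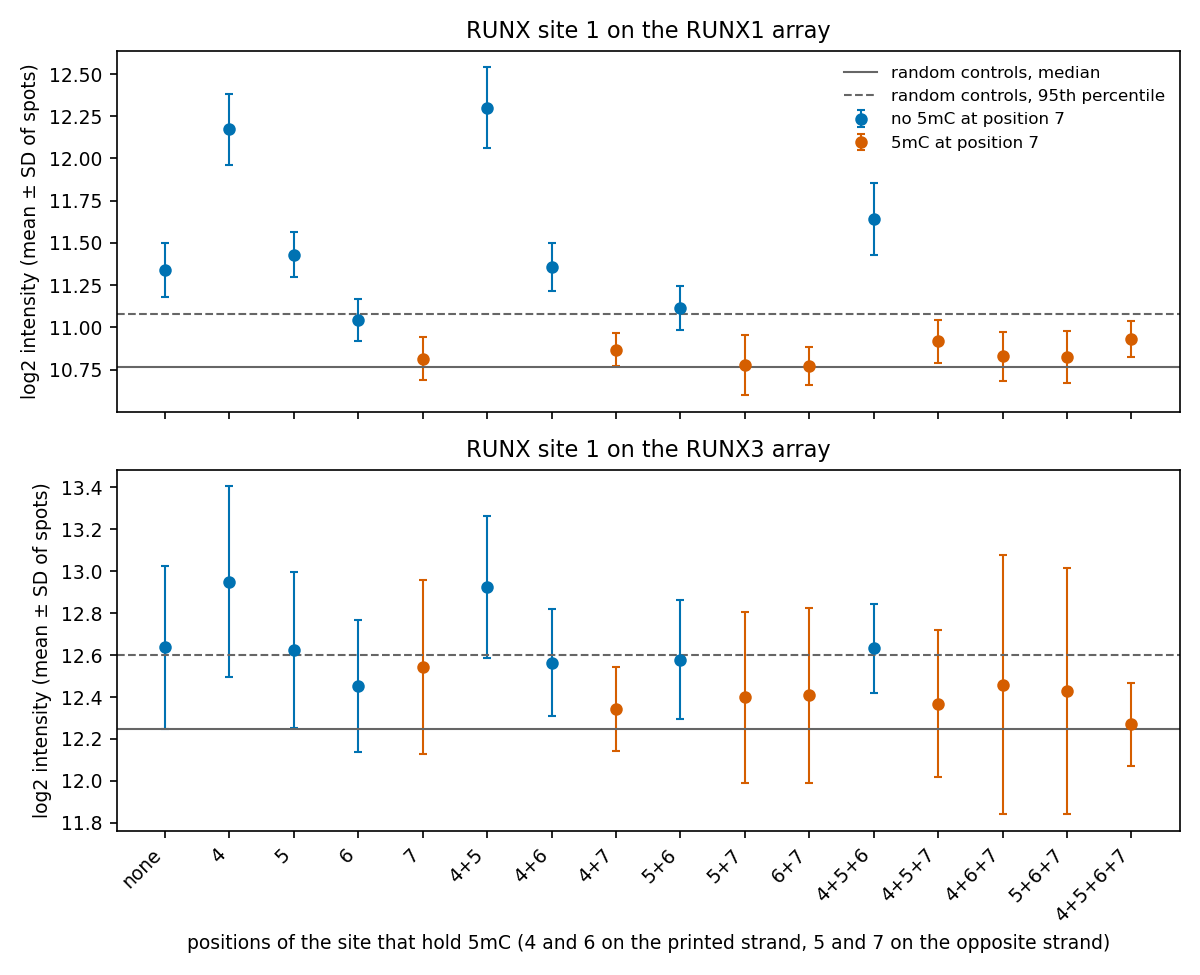
Mean log2 intensity of the 16 methylation states of RUNX site 1 on the RUNX1 array (top) and the RUNX3 array (bottom), with bars for the SD between spots. Lines mark the median and the 95th percentile of the randomized controls. On the RUNX1 array the 8 states with 5mC at position 7 lie at 10.93 or below, and the brightest state, with 5mC at positions 4 and 5, lies at 12.30.

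Over all tested pairs, 29 of 86 CpG pairs were lower with 5mC and 18 were higher on the RUNX1 array, of which 20 and 12 were hemi-methylated and 9 and 6 fully methylated. The 86 include 9 pairs of the MTF1 site and 3 of the longer RUNX site, whose unmodified forms lay under the 95th percentile of the controls. The RUNX3 array gave 7 of 55 lower and 4 higher. Of the 14 pairs of site 1 among these, 0 were lower and 2 were higher. Site 1 lay just above the filter on that array, so a fall could drop a pair from testing while a rise could not. Without the filter, falls of the core CpG of site 1 passed, as given above. On the HOXB13 array 3 of 60, which include 30 of the MTF1 site and 1 of the flipped RUNX site, were higher and 0 were lower. For the 0, limma gave 6 lower pairs at an unadjusted p under 0.05 and the permutation test gave 0 after adjustment. In HOXB13 site 2 the core CpG at positions 7 and 8 did not pass in any state: full methylation changed the signal by 0.07 (SE 0.04, adjusted p = 0.35), 5mC on the printed strand by -0.08 (SE 0.03, adjusted p = 0.15) and 5mC on the opposite strand by 0.04 (SE 0.04, adjusted p = 0.54), and a CpG at the edge of the site, with 5mC opposite position 1, by 0.03 (SE 0.04, adjusted p = 0.72). The signal of the fully methylated site was 120% (95.8 to 150) of the unmethylated one. The 3 that passed were listed as variants of HOXB13 site 1 and were named after their values were seen. With T7C and T8G, which make a CpG at the same place, 5mC on the opposite strand raised the signal by 0.19 (SE 0.03, adjusted p = 4.20e-06) and full methylation by 0.14 (SE 0.03, adjusted p = 0.0018). The sequence with T7C and T8G is also the A9G variant of site 2. Both of these rises and that of 0.17 for 5mC opposite position 9 therefore share a reference. With G10C, 5mC opposite position 11 raised it by 0.10 (SE 0.03, adjusted p = 0.045). None of these passed with spots taken before the spatial correction.

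**Figure D3:**
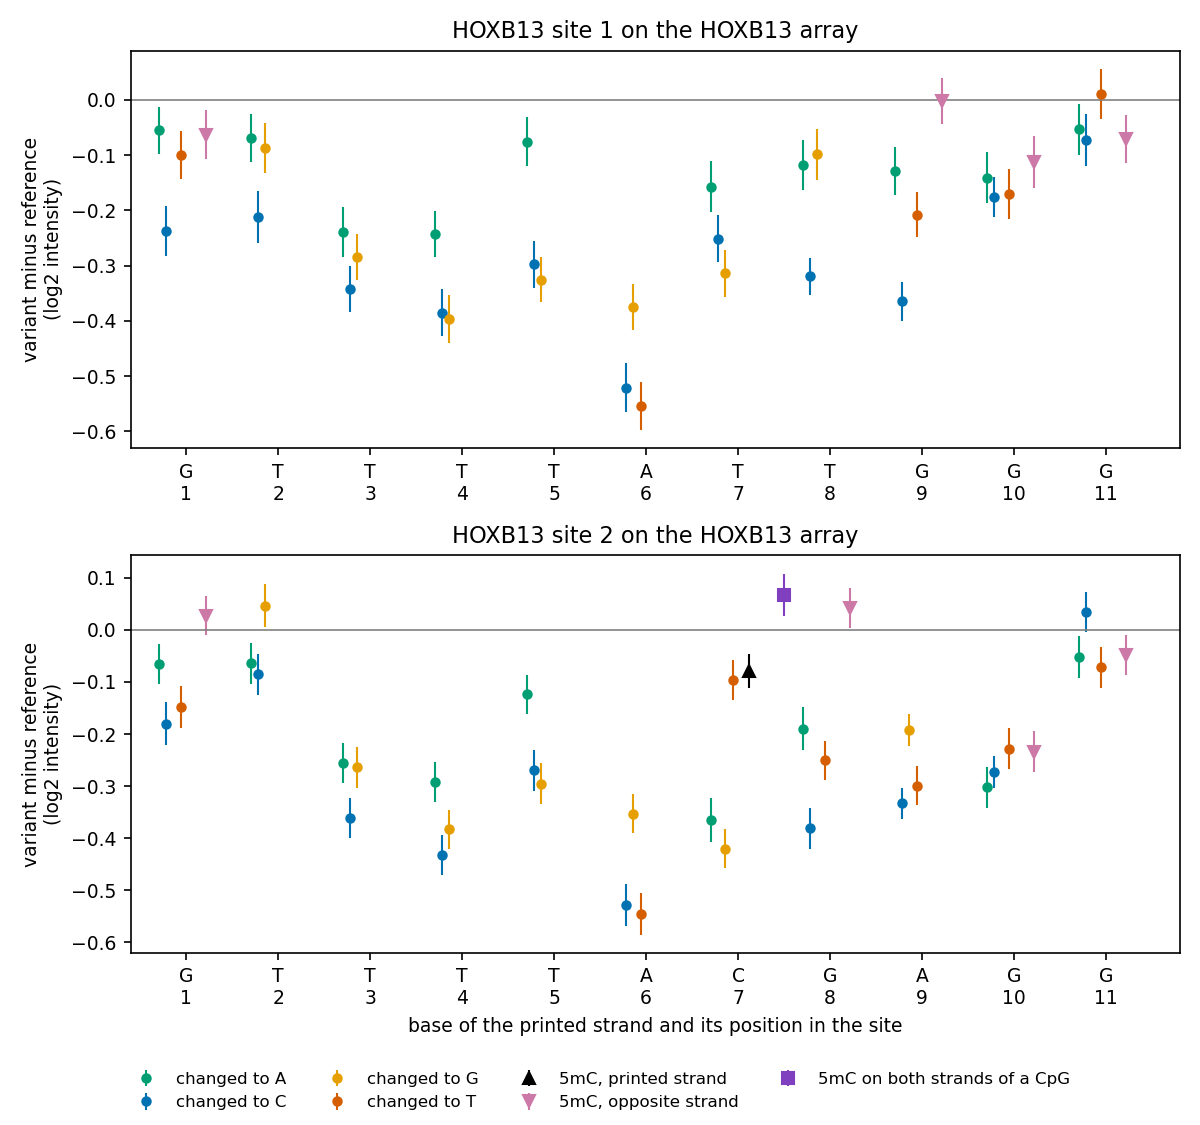
Changes of log2 intensity for variants of HOXB13 site 1 (top) and site 2 (bottom) against the unmodified site on the HOXB13 array, by position in the site. Circles are base substitutions coloured by the new base, triangles are 5mC on the printed or the opposite strand, squares are CpGs methylated on both strands, and bars are the SE from limma over spots. The changes at position 6 reach -0.55 in both sites, and the methylated core CpG of site 2 lies between -0.08 and 0.07.

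5mC outside the binding site served as a control in the flanks of RUNX site 1. For RUNX1, 5 of 18 such sequences were higher, by 0.10 to 0.24, and 0 were lower by limma, with 1 lower at an unadjusted p under 0.05 and 0 by the permutation test. 4 of the 5 also changed a base, so that 1 of the 8 sequences with unchanged bases passed, at 0.15 (SE 0.04). With normexp background correction 2 were higher and 3 lower. For RUNX3, limma called 0 of 13, with 1 at an unadjusted p under 0.05 and 0 by the permutation test. On the HOXB13 array no pair passed the filter.

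The proteins were then compared on the same sequences. Across all 722 sequences the mean log2 intensities of the RUNX1 and RUNX3 arrays correlated at r = 0.87 (rho = 0.72), whereas RUNX1 and HOXB13 correlated at r = -0.13 (rho = -0.03) and RUNX3 and HOXB13 at r = -0.16 (rho = -0.03). These values are across sequences, which are not independent replicates. For 153 pairs tested on both RUNX arrays, the change differed between the arrays in 65 (limma interaction, adjusted p under 0.05), 51 of 78 substitutions, 3 of 21 pairs with 5mC outside CpG and 11 of 54 CpG pairs. In 60 of the 65 the changes had the same sign, and in 64 the change was larger on the RUNX1 array. Site 2 and the flipped site are the same duplex, so the 153 pairs are not all separate changes. In place of 65 of 153 pairs, 16 of 99 differed with spots before the spatial correction, 25 of 123 with normexp and 20 of 91 with both sequences above the threshold on both arrays. When each change was divided by the range of its array, 2 of the 153 still differed: G11A in site 1, and full methylation of positions 4 and 5 in site 1, both larger on the RUNX1 array. The brightest sequences, which set these ranges, are themselves among the pairs. For RUNX1 against HOXB13 only 14 pairs could be tested, and 4 differed, all in the MTF1 site. With 1 array per protein, these tests compare the arrays and not the proteins in general.

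**Figure D4:**
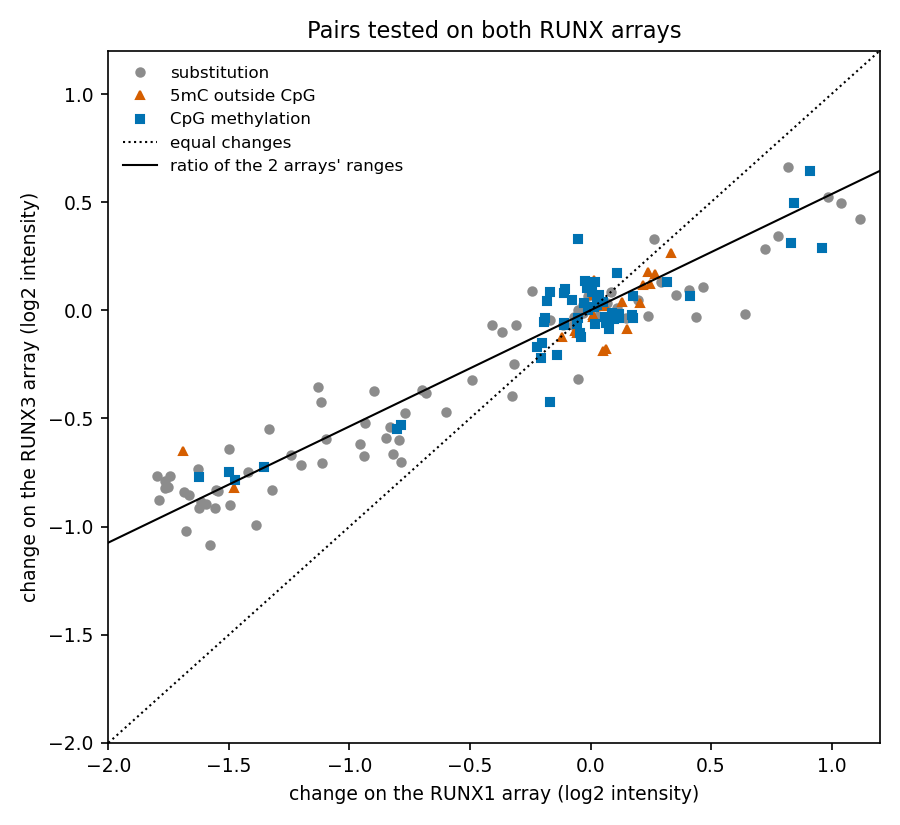
Change of log2 intensity on the RUNX1 array (horizontal) and the RUNX3 array (vertical) for the 153 pairs tested on both, by kind of pair. The dotted line marks equal changes and the solid line the ratio of the ranges of the arrays, 0.54. The slope of the points is 0.50.

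Lists of sequences holding a core, fixed before the data were examined, were then compared with the other sequences, with 5mC read as C. Most sequences with a RUNX core, 82 of 86 with TGCGGT and 40 of 41 with TGTGGT, were variants of RUNX sites 1 to 3. Of those with a HOXB13 core, 34 of 34 with TTTATT, 40 of 41 with TTTACG and 3 of 3 with TTTATG were variants of the HOXB13 sites, so these lists restate the design and are no independent test. The 86 sequences with TGCGGT had a median 1.21 above the other sequences on the RUNX1 array and 0.74 above on the RUNX3 array, higher than 100% of 10000 random lists of the same size on both, and 0.01 above on the HOXB13 array (76.3%). The 41 with TGTGGT lay 0.61 above on the RUNX1 array (100%) and 0.15 above on the RUNX3 array (98.7%). On the HOXB13 array TTTATT (34 sequences), TTTACG (41) and TTTATG (3) lay 0.23, 0.28 and 0.29 above, at the 100th, 100th and 99.2th percentile. Restricted to unmethylated sequences, the 36 with TGCGGT lay 1.45 above the rest on the RUNX1 array. Among the control cores, CACGTG, TGACGTCA, TTGCGCAA and GCGTGGGCG occurred in 0 sequences. The 104 sequences with CCGCG lay 0.30 and 0.34 above on the RUNX1 and RUNX3 arrays (100% each) and 0.01 above on the HOXB13 array (89.9%), but 81 of them were variants of RUNX sites 1 to 3, so this list is no independent control. The 4 with CCGGAA lay -0.16, 0.02 and 0.01 from the rest on the RUNX1, RUNX3 and HOXB13 arrays (6.29%, 50.5% and 52.3%). All 4 were variants of RUNX sites 1 to 3, so this list is no independent control either. The 10 with GGGCGG lay 0.28, -0.03 and 0.17 from the rest (95.6%, 37.9% and 99.9%). They include variants of the MTF1 site, which itself lay above the controls on the HOXB13 array.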

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

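The tests of the array range here were chosen after the result was seen, and the test of uneven signal on the RUNX3 array before. A difference between arrays in the limma interaction marked 65 of the 153 pairs tested on RUNX1 and RUNX3, and 4 of the 14 tested on RUNX1 and HOXB13. With spots before the spatial correction 16 of 99 tested pairs differed between RUNX1 and RUNX3, with normexp 25 of 123, and with both sequences above the threshold on both arrays 20 of 91. Among the named sequences the RUNX1 change minus the RUNX3 change was, for substitutions in RUNX site 2, -0.91 for G7C, -1.03 for G7A, -0.98 for G8A, 0.54 for G11A and 0.44 for G11T. For substitutions in the flipped site it was -0.66 for C5T, -0.50 for C7T, -0.39 for G6T, 0.43 for C1A and 0.46 for C1T. For 5mC outside CpG it was -1.04 opposite position 8 of site 2 and -0.66 at position 4 of the flipped site. For the core CpG it was -0.85 with full methylation, -0.75 with 5mC opposite position 7 and -0.25 with 5mC at position 6 in site 2, and -0.69, -0.63 and -0.25 for the same states of the flipped site. For the second CpG it was 0.67 with full methylation in site 1, and 0.35 with full methylation and 0.27 with 5mC opposite position 8 in the A8G variant of the flipped site. In all of these the change had the same sign on both arrays and was larger on the RUNX1 array. Many of the falls end at the level of the controls on both arrays, so their size is set by how far the reference lies above the controls, 1.69 on RUNX1 and 0.81 on RUNX3 for site 2, and says nothing of which protein depends more on the base.

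The log2 range of the RUNX3 array was 0.54 of that of the RUNX1 array, and after each change was divided by its array's range 2 of the 153 pairs still differed. This decides nothing, since the brightest sequences that set the ranges are themselves in the pairs, so that a smaller range of the array and weaker discrimination by the protein cannot be told apart with 1 array per protein. Uneven signal across the RUNX3 array argues less well. In the less corrected spots the slope of the RUNX3 change on the RUNX1 change was 0.53, and in the more corrected spots 0.48, a difference of 0.0568 (95% interval 0.02 to 0.10), and neither slope came near 1. A difference in sequence preference between the proteins stays open too.

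The calibration oligonucleotides, which no comparison used, were brighter than the 95th percentile of the empty spots in 3 cases. PUC2MM and PUC2PM had median spot means of 3208 and 3098 on the RUNX1 array against 3045 for that percentile, and PUC2PM-68-X had 4518 on the RUNX3 array against 4429. These means are not spatially corrected.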

How the results depend on the processing

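The filter from the controls without 5mC and the removal of the GC trend were chosen after the data were seen. No pair called in the main setting was called with the opposite sign under the alternative settings, a check that did not cover leaving out spot copies. Of the named sequences, 1 lost its call through the values: full methylation in the A8G variant of the flipped site 2 on the RUNX3 array, at 0.36 (adjusted p = 0.22) before the spatial correction. Another 7 fell under 1.5-fold by the construction of that threshold. Counts called at 1.5-fold or more, in the order RUNX1, RUNX3, HOXB13, were 67, 33 and 0 for substitutions against 112, 53 and 60, 4 and 0 for 5mC outside CpG on RUNX1 and HOXB13 against 18 and 3, 11, 5 and 0 for CpG methylation against 47, 11 and 3, and 0 for 5mC outside the site on RUNX1 against 5. With spots before the spatial correction they were 26 and 25 for substitutions on RUNX3 and HOXB13, 1 and 0 for 5mC outside CpG, 0 for CpG methylation on HOXB13 and 3 for 5mC outside the site on RUNX1. With normexp they were 31 for substitutions and 1 for 5mC outside CpG on RUNX3. Without the filter the RUNX3 counts were 107, 5 and 18 for substitutions, 5mC outside CpG and CpG methylation, as more pairs were tested. For 5mC outside the site on RUNX3, 0 became 1 with saturated spots removed, and leaving out 1 spot copy gave 0 to 1. In every other class, leaving out a spot copy kept the total count within 1.5 times. Split into lower and higher, 10 counts moved beyond that when a spot copy was left out, against 5 total counts. The pairs that differed between RUNX1 and RUNX3, 65 of 153 tested, became 16 of 99 before the spatial correction, 25 of 123 with normexp, 20 of 91 with both sequences above the threshold on both arrays and 2 of 153 after division by the range. Those between RUNX1 and HOXB13, 4 of 14, became 2 of 9 with normexp, 1 of 8 with both sequences above the threshold and 1 of 14 after division. The 1.5-fold and unfiltered settings act by construction. Division by the range decided nothing, as described above, and for the other settings the cause was not tested. The number of bound sites stayed within 1.5 times. It rose from 4 to 6 on RUNX1 and from 3 to 4 on RUNX3 with either added setting, and fell to 2 on RUNX3 with the 99th percentile or the median of spots. The series values and the kept flagged spots moved no count of calls beyond 1.5 times. The low signal over background of the HOXB13 array, a range of 0.62, limits what it can show. No paired analysis was possible because each protein has 1 array.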

Other observations

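The tests of thymine-like reading and of the oligonucleotide itself were chosen after the results were seen, and those of the methyl group and of GC content in the controls before. Base changes in the MTF1 site and the longer RUNX site raised the RUNX1 signal in 3 cases, all named after their values were seen. These sites lay under the 95th percentile of all controls on the RUNX1 array but above that of the controls without 5mC. The 3 were the only substitutions of these sites that were tested on this array. With the references under the filter only a rise could pass it, so their direction was fixed in advance. In the MTF1 site A10G, which makes the core TGCGGT, rose by 0.41 (SE 0.03), and in the longer RUNX site G9T, which makes TGTGGT, rose by 0.38 (SE 0.04). C2G in the MTF1 site makes GGGCGG and rose by 0.31 (SE 0.03). In the A10G variant 5mC opposite position 10 lowered the signal by 0.30 (SE 0.03), full methylation by 0.27 (SE 0.04) and 5mC at position 9 of the printed strand by 0.14 (SE 0.04), so the CpG of this core lost more signal from the opposite strand than from the printed one, as in RUNX site 2. All of these passed limma on the RUNX1 array.

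On the RUNX1 array 5mC raised the signal at some positions and lowered it at others. Over the 65 methylation pairs called on RUNX1, the slope of the HOXB13 change on the RUNX1 change was 0.0019 (95% interval -0.0085 to 0.012). The largest HOXB13 change was 0.06, while the slope on the RUNX3 array was 0.46. These values argue against a shift of background signal by the oligonucleotides themselves. HOXB13 did not bind RUNX sites 1 to 3, which most of these pairs vary. An effect of the oligonucleotides on bound signal could therefore not show on that array, and stays open. Another hypothesis is that 5mC is read like thymine, which carries a methyl group at the same place. Over 65 sets of sequences with C, 5mC and T at a position, with the C spots split between both differences, 5mC minus C correlated with T minus C at r = 0.61 (95% interval 0.31 to 0.80, permutation p = 2e-05; rho = 0.33, permutation p = 0.0074). It correlated less with A minus C, at r = 0.46, a difference of 0.15 (95% interval 0.02 to 0.32). With G minus C it correlated nearly as well, at r = 0.59, and the difference of 0.02 had an interval of -0.09 to 0.15. The sets are not independent, since sets of a site share a reference and site 2 and the flipped site are the same duplex. The intervals and permutation p-values of these correlations may therefore overstate the precision. The changes to 5mC and to T had the same sign in 38 of the 65 sets. Opposite position 5 of site 2, 5mC raised the signal by 0.22 while T on that strand, the change G5A, changed it by -1.68, so reading as thymine does not hold at every position and stays open elsewhere. At 2 core positions, picked with their values known, 5mC lay nearer to T than to A or G. At position 6 of site 2, 5mC changed the signal by -0.78 and C6T by -0.82, against -1.55 for the other bases. At position 4 of site 1, 5mC gave 0.83 and C4T 1.12, against -0.01 and -0.12 for the other bases. 5mC lay closer to T than to C in 26 of the 65 sets.

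Randomized controls with 5mC were brighter than those without by 0.26 on the RUNX3 array (permutation p = 0.001, adjusted 0.0031), by 0.13 on RUNX1 (permutation p = 0.0052, adjusted 0.0077) and by 0.05 on HOXB13 (permutation p = 0.038, adjusted 0.038). The methyl group argues poorly: over 226 pairs under the threshold on RUNX3, 5mC minus C had a median of -0.019 (95% interval -0.03 to -0.0012). GC content is a candidate explanation on that array, since the controls with 5mC had 75.7% GC and the others 63.8%, and the slope over the 16 controls without 5mC predicts a gap of 0.24 (95% interval 0.20 to 0.28). On RUNX1 that slope predicts 0.03 (95% interval -0.03 to 0.10). With the GC trend removed, RUNX site 3 lay above the controls on the RUNX3 array, at 0.21 against a threshold of 0.15, and all 53 RUNX3 substitutions called before were among the 61 called.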
